A study of Mus musculus with 10 samples.

How the data were processed

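RNA was measured on Affymetrix GeneChip 430 2.0 arrays, which read each transcript with 1 or more probe sets. The 10 arrays came from 3 groups of mouse cells. AG-haESC are androgenetic haploid embryonic stem cells, derived from blastocysts that carry a paternal genome only, and 5 lines of C57BL/6J background were measured, each on 1 array. Of these, 4 lines carried an Oct4-EGFP transgene (AGH-OG-1 to AGH-OG-4, here AG-haESC replicates 1, 2, 4 and 5) and 1 carried an Actin-EGFP transgene (AGH-EG-1, here AG-haESC replicate 3). E14 is a male diploid embryonic stem cell line of 129/Sv background, measured on 3 arrays. MEF are mouse embryonic fibroblasts, per each label from a male embryo of day 13.5 (B6D2F1), measured on 2 arrays, and whether both came from the same embryo is not given in the sources used here. Per the labels, cells were stained with Hoechst 33342 at 15 µg/ml and sorted, the haploid 1n peak for AG-haESC and the diploid 2n peak for E14 and MEF. The growth protocol names feeder cells and the inhibitors CHIR99021 and PD0325901 for AG-haESC, and the medium of the E14 and MEF cultures is not given in the sources used here. AG-haESC and E14 differ in ploidy, in parental origin of the genome, in strain and in passage at once. The AG-haESC lines also carried EGFP transgenes, and their culture may have differed from that of E14. The design does not separate these.

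The deposited values are signal intensities per probe set, which the authors made with MAS5 per the labels, on a linear scale. The 2% trimmed mean of every array was 500, which is the scaling of that method, and no log had been taken and no probe set removed. Array medians lay between 55.9 and 68.0. The scanner software, the software version and the detection calls are not given in the sources used here. The scaling fixes the mean of each array, so a change in the total RNA per cell cannot be seen, and values are relative within each array. Signals near or below the array median hold much background, which compresses or inflates differences there.

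Signals were taken to log2. Of 45101 probe sets, 64 were controls, 34945 paired with exactly 1 gene symbol, 932 with several and 9160 with none listed. A probe set was kept if its signal lay above the array's own median in at least 2 arrays, which left 27505. For each gene the kept probe set with the highest mean log2 signal over the 10 arrays was used, among those that pair with 1 symbol, which gave 13251 genes, 6177 of them with several kept probe sets. Chromosomes came from the gene table of assembly GRCm38.p6, used for names and chromosomes alone. H19 shares its probe set with Mir675 and is not reported, and Ddx3y was not analysed here because the probe table lists no probe set for it.

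Genes were tested with limma 3.58.1 in R 4.3.3, with all 10 arrays in 1 fit of 3 group means, 7 residual degrees of freedom and a prior variance that follows the signal. P-values are two-sided and were adjusted by Benjamini-Hochberg over the genes of each comparison. A gene is called changed when its adjusted p lies below 0.05 and its difference is at least 2-fold, and "higher" and "lower" for counts of genes refer to these calls. Values of genes are mean log2 signals with SD over arrays, and differences carry the standard error of the fit. Where every array of the dimmer group lay below its own array median, the difference is given as "at least", with the dimmer group put at the array medians. The number of arrays limits the precision of every value. The AG-haESC arrays are of separate lines, while all E14 arrays are of the same line. The SD, SE and p-values that involve E14 thus hold no spread between diploid lines. In a test on simulated data, with 100 genes changed by 1.5 log2 units and 100 by 3 log2 units added to noise of the measured size, 58% and 88% were called for AG-haESC against E14 with 7 false calls, 59% and 90% for AG-haESC against MEF with 6, and 55% and 85% for E14 against MEF with 6. The simulated noise was independent between genes, with the same SD in every group, and fewer genes changed than were called in the data. These rates and false calls hold for that setting and need not carry over to the data.

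Before the data were examined, 24 gene lists were fixed. They cover pluripotency, primed epiblast, lineage differentiation, targets of ERK signalling, of WNT signalling and of p53, paternally and maternally expressed imprinted genes, fibroblast markers, epithelial junctions, Hox genes, genes of the 2-cell stage, germline genes, DNA methylation, the G1/S and G2/M phases, glycolysis, oxidative phosphorylation, the interferon response, macrophages, endothelium, muscle, neural genes and Y-linked genes. The X-linked genes made the list number 25. Lists were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 25 lists. For each array a list value was computed, the median of the gene-centred log2 signals of the list minus that of the other genes (autosomal genes for the X), and groups were compared by exact permutation of the arrays. With 5 against 3 arrays there are 56 splits and the smallest two-sided p is 0.0179. With 5 against 2 the smallest is 0.0476, and with 3 against 2 it is 0.1, so that test cannot reach 0.05 for E14 against MEF.

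The groups, the comparisons, the thresholds, the lists and the alternatives were fixed before the data were examined, apart from a few alternatives named in the closing section. The genes named in the text were chosen by a rule fixed at the same time. It takes for each comparison the 10 largest changes in each direction among changed genes whose groups did not overlap, whose brighter group lay above the array medians and whose probe set pairs with 1 symbol, and up to 4 of the largest changed members of each list. It also takes Pou5f1, Nanog, Sox2, Zfp42, Klf4, Esrrb, H19, Igf2, Meg3, Snrpn, Peg3, Igf2r, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Col1a1, Thy1, Cdkn1a, Nnt, Dnmt3b and Cdh1 whatever their values. The text gives part of the genes that the rule takes. The alternatives were quantile normalization, a pseudocount of 32, a floor at the array median, no filter, a stricter filter, all probe sets, the mean of the probe sets of a gene, another probe set of the gene, a fit of 2 groups alone, no trend, array weights, other thresholds, a replicate block and leaving out each array in turn.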

Results

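The arrays covered 3 groups of sorted mouse cells, with 5 AG-haESC lines, 3 E14 arrays and 2 MEF arrays, and 13251 genes were tested in each of 3 comparisons. Array medians ranged from 55.9 to 68.0 on the linear signal scale, against a trimmed mean of 500 in every array. Across genes, Pearson's r of log2 signals averaged 0.960 between AG-haESC lines, 0.938 between E14 arrays and 0.969 between the MEF arrays. Between groups it averaged 0.914 for AG-haESC and E14, 0.661 for AG-haESC and MEF and 0.652 for E14 and MEF. Genes are not independent replicates, so these coefficients describe similarity and carry no test. The first principal component held 66.2% of the variance and separated MEF from both stem cell groups, and the second held 12.6% and separated AG-haESC from E14. The third held 6.82%, and on it E14 replicate 3 scored 73.0 against -32.2 and -33.4 for E14 replicates 1 and 2. The median SD of a gene was 0.29 log2 units among AG-haESC lines and 0.33 among E14 arrays, where it was 0.12 over E14 replicates 1 and 2 alone.

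The comparison of AG-haESC with E14 asks how haploid stem cells with a paternal genome differ in expression from a diploid male stem cell line. All E14 arrays came from that same line, so the calls below need not hold for other diploid lines. X-linked genes stood higher in AG-haESC as a class, Y-linked transcripts lay below the array medians, and imprinted genes differed in both directions. Plagl1, a paternally expressed zinc finger gene, was at 13.23 ± 0.15 against 9.73 ± 0.48 (mean log2 signal ± SD, n = 5 and n = 3), a difference of 3.51 ± 0.18 (SE) with adjusted p = 1.41e-06. Phlda2, a maternally expressed gene that limits placental growth, was at 8.97 ± 0.42 against 11.83 ± 0.46, a difference of -2.86 ± 0.26 with adjusted p = 5.98e-05. The pluripotency factors Pou5f1 and Sox2 differed by 0.030 ± 0.13 and -0.041 ± 0.16 (adjusted p = 0.908 and 0.896). Of 13251 genes, 607 were higher and 495 lower in AG-haESC, 1102 in all, and 2101 passed the adjusted p alone. The numbers higher and lower were 520 and 324 without E14 replicate 1, 553 and 297 without E14 replicate 2 and 677 and 664 without E14 replicate 3. Over all 13251 genes, called or not, the groups' arrays did not overlap for 3000, where chance gives 3.57% of genes. For 210 of the 1102 the dimmer group alone lay below the array medians, so that their size is a lower bound, and 42 more, with a group or both below them, have no bound.

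**Figure D1:**
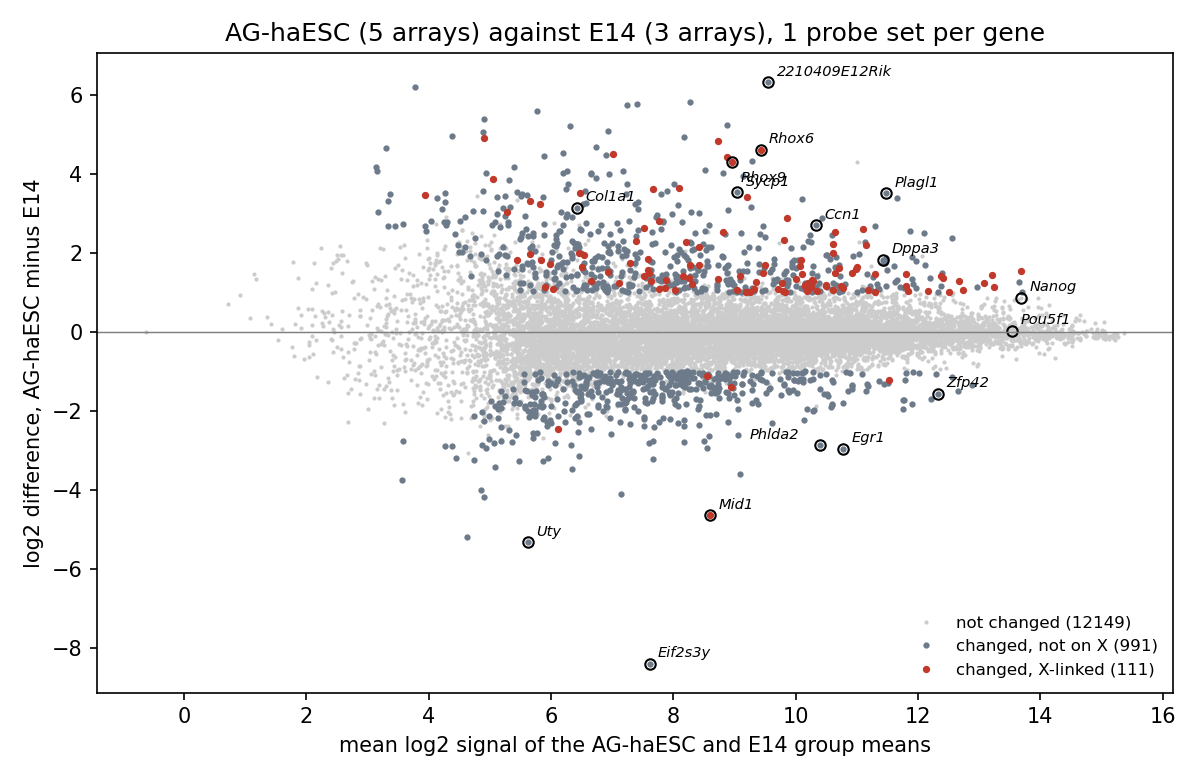
Difference in log2 signal between AG-haESC (5 arrays) and E14 (3 arrays) against the mean log2 signal, with 1 point per gene, changed X-linked genes in red, other changed genes in dark grey and the rest in light grey. Of the changed X-linked genes 106 lie above 0 and 5 below, and the Y-linked genes Eif2s3y and Uty lie lowest, where AG-haESC signals were below the array medians and the plotted differences are no bound.

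Of 465 X-linked genes tested, 106 were higher in AG-haESC and 5 were lower, against 499 and 486 of 12757 autosomal genes (odds ratio for higher 7.25, Fisher's exact p = 8.34e-46). Fisher's test takes genes as independent, which genes of the same arrays are not, so its p does not measure the spread between arrays. The shift was not confined to the called genes, since 83.9% of X-linked genes had a positive difference against 41.1% of autosomal genes. The X value of an array, the median of its X-linked genes minus that of its autosomal genes, was 0.36 ± 0.12 in AG-haESC (SD, n = 5) and -0.37 ± 0.054 in E14 (n = 3). The difference was 0.74, and an exact permutation test over 56 splits gave p = 0.0179, the smallest it can give (0.0893 adjusted over 25 lists). The lowest AG-haESC value was 0.16 in AG-haESC replicate 2 and the highest E14 value -0.34, and on the same scale the autosome farthest from 0 in a stem cell array was chromosome 6 in E14 replicate 3, at -0.13. Adjusted over the list alone, 123 X-linked genes were higher and 6 lower. The camera test of the X-linked list gave adjusted p = 1.4e-29, and adjusted p = 0.0850 with an estimated correlation. The number lower was 3 without E14 replicate 1 or without E14 replicate 2.

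**Figure D2:**
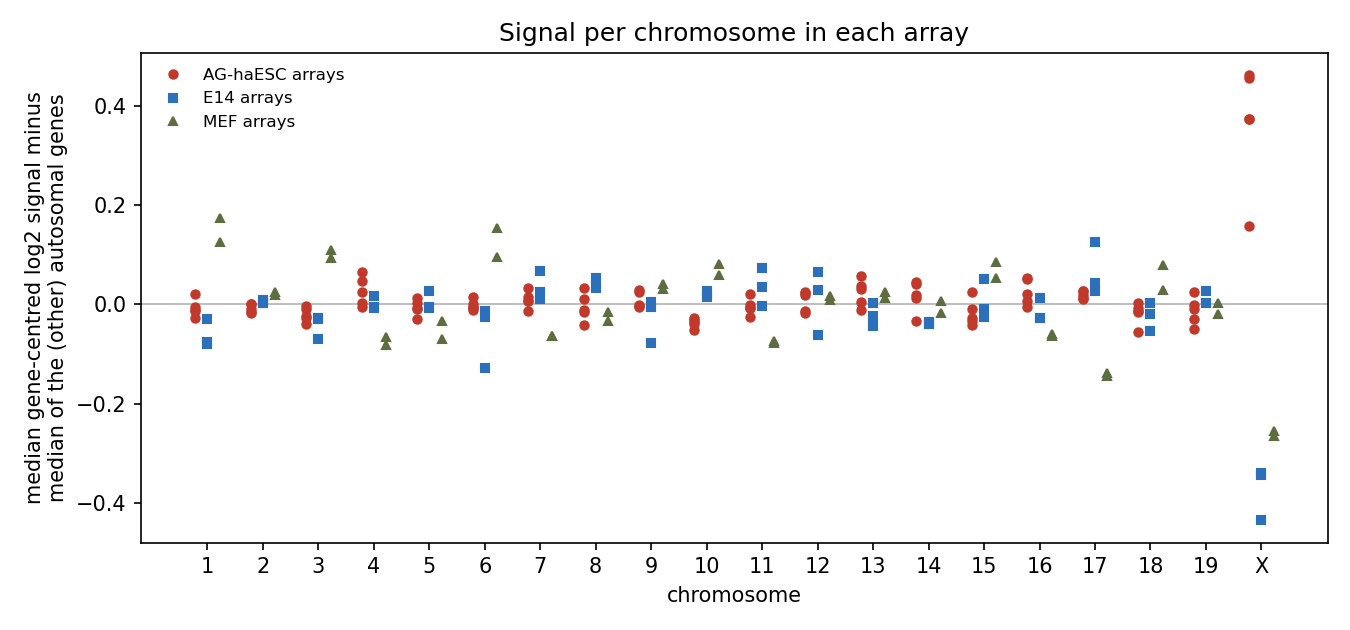
Median gene-centred log2 signal of each chromosome minus that of the (other) autosomes, with 1 point per array and chromosomes along the axis. On the X chromosome the 5 AG-haESC arrays lie between 0.16 and 0.46 and the 3 E14 arrays between -0.44 and -0.34, while the 2 MEF arrays lie at -0.26 and -0.25.

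Of the X-linked genes named by the rule, Magea5, of the melanoma antigen family, was at 11.14 ± 0.84 against 6.32 ± 2.05, Rhox6, a reproductive homeobox gene, at 11.73 ± 0.47 against 7.12 ± 0.63 and Rhox9 at 11.11 ± 0.63 against 6.80 ± 0.63, differences of 4.83 ± 0.74, 4.61 ± 0.32 and 4.31 ± 0.48 (adjusted p = 0.00139, 1.17e-05 and 0.000205). Magea5 read 3.95 in E14 replicate 3 against 7.50 in each of the other E14 arrays, and without E14 replicate 3 its difference was 3.65, below those of Rhox6 and Rhox9. Mid1, which spans the boundary of the pseudoautosomal region in laboratory mice, went the other way at 6.28 ± 1.10 against 10.91 ± 0.34, a difference of -4.64 ± 0.52 (adjusted p = 0.00021). Xist, the RNA that coats an inactive X chromosome, was at 8.69 ± 0.088 against 7.75 ± 0.58 and did not pass the test (adjusted p = 0.236). The 4 measured Y-linked genes were lower in AG-haESC (camera adjusted p = 0.000361, adjusted p = 0.0850 with an estimated correlation), and adjusted over the list alone the count was again 4. Eif2s3y was at least 57.7-fold lower and Uty at least 4.98-fold lower. Kdm5d was at least 1.26-fold lower (adjusted p = 0.0322), and its call was lost without any 1 of AG-haESC replicates 1, 3, 4 and 5 or of E14 replicates 1 and 2, with adjusted p between 0.0526 and 0.142. It read 3.62 in E14 replicate 3, inside the AG-haESC range of 2.80 to 3.90, against 7.61 and 7.65 in E14 replicates 1 and 2. The bound was 3.19-fold without E14 replicate 3, and there was none without E14 replicate 1 or E14 replicate 2. Without E14 replicate 1 the number of Y-linked genes lower was 2.

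Of 22 paternally expressed imprinted genes, 5 were higher in AG-haESC and 1 was lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00345, adjusted p = 0.0850 with an estimated correlation). Besides Plagl1, Peg12 was higher by 1.88 ± 0.26, Peg3, a regulator of growth and maternal behaviour, by 1.75 ± 0.18 and Nap1l5 by 1.58 ± 0.29. The 1 lower member, Inpp5f, chosen after its values were seen, was at 7.90 ± 0.37 against 9.45 ± 0.46, a difference of -1.55 ± 0.26. Igf2, the growth factor, was at 8.80 ± 0.66 against 8.10 ± 1.11 and Snrpn at 5.78 ± 1.19 against 6.21 ± 0.59, and neither passed the test (adjusted p = 0.327 and 0.706). The list value per array was 0.15 ± 0.12 in AG-haESC and -0.44 ± 0.26 in E14, a difference of 0.60 (exact permutation p = 0.0179, the smallest it can give, 0.0893 adjusted over 25 lists). In that test the X-linked, Y-linked, germline and Hox lists gave the same p. The ERK, primed, lineage and interferon lists gave 0.0357 (0.0992 adjusted), and the remaining lists gave a larger p. No list passed after adjustment.

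Of 26 maternally expressed imprinted genes, 7 were lower in AG-haESC and 1 was higher, again with the same counts adjusted over the list alone (camera adjusted p = 0.0356, adjusted p = 0.241 with an estimated correlation). With Phlda2 the largest decreases were in Cdkn1c, an inhibitor of cyclin-dependent kinases, by -2.76 ± 0.59, and in Rian, a noncoding RNA of the Dlk1-Meg3 locus, by -2.24 ± 0.29. Meg3 of the same locus was at 10.40 ± 0.50 against 11.90 ± 0.57, a difference of -1.50 ± 0.29 (adjusted p = 0.00606). Cdkn1c read 10.76 in E14 replicate 3 against 8.24 and 8.14 in E14 replicates 1 and 2, and without E14 replicate 3 its difference was -1.90. On other probe sets Rian was called in 1 of 3 and Meg3 in 5 of 10, where Meg3 read from -3.21 to -0.32. Igf2r differed by -0.21 ± 0.29 (adjusted p = 0.66). The 1 higher member, Dcn, chosen after its values were seen, also stands in the fibroblast list, and its difference of 1.67 ± 0.46 was no longer called without any 1 of AG-haESC replicates 2, 3 and 5 or of E14 replicates 1 and 3 (adjusted p between 0.0654 and 0.0926). The list value per array was -0.45 ± 0.38 in AG-haESC and -0.015 ± 0.20 in E14, a difference of -0.44 that did not pass (exact permutation p = 0.0893). It was -0.24 without AG-haESC replicate 1, whose own value was -1.10. The camera call of the list was lost without AG-haESC replicate 1, AG-haESC replicate 4 or E14 replicate 3 (adjusted p = 0.0639, 0.0589 and 0.1003), and with the mean of probe sets (0.0927).

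**Figure D3:**
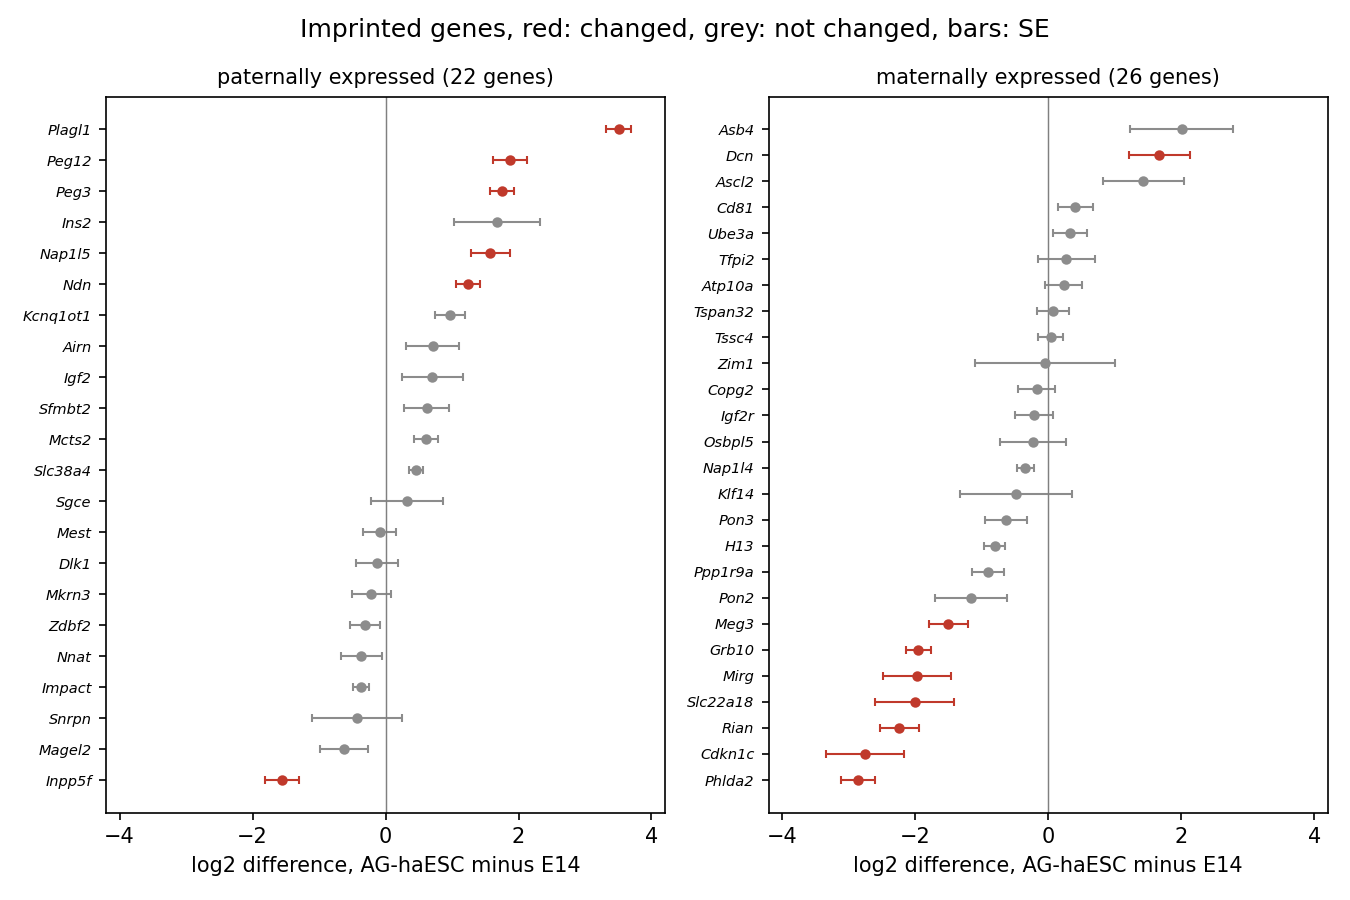
Difference in log2 signal between AG-haESC (n = 5) and E14 (n = 3) for 22 paternally and 26 maternally expressed imprinted genes, with points for the differences, bars for their SE, and changed genes in red. Plagl1 reaches 3.51 at the upper end of the first group and Phlda2 -2.86 at the lower end of the second.

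The pluripotency list was little changed, with 2 of 31 measured members higher in AG-haESC and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0959, and 0.0306 with a floor). Nanog, a core factor of the pluripotent state, stood at 14.12 ± 0.072 against 13.25 ± 0.23 and passed the adjusted p (0.00075) with a difference of 0.87 ± 0.12, below 2-fold. Klf4 and Esrrb differed by 0.30 ± 0.24 and 0.10 ± 0.17 and did not pass (adjusted p = 0.436 and 0.738). Dppa3, a maternal factor that protects DNA methylation, was higher by 1.83 ± 0.35 (adjusted p = 0.00555) and Prdm14 by 1.43 ± 0.37 (0.0231). Zfp42, a marker of naive stem cells also named Rex1, was lower by -1.56 ± 0.40 (0.0219) and the RNA-binding gene Lin28a by -1.57 ± 0.42 (0.0277). The Prdm14 call was lost without any 1 of AG-haESC replicates 1 and 2 or of E14 replicates 1 and 2 (adjusted p between 0.0506 and 0.0577). The Zfp42 call was lost without E14 replicate 2 or E14 replicate 3 (0.0502 and 0.0532). The Lin28a call was lost without AG-haESC replicate 1 or any 1 of the 3 E14 arrays (between 0.0516 and 0.0717). Without E14 replicate 3 there were 6 members higher and the list's camera adjusted p was 0.00177, and without AG-haESC replicate 4 it was 0.0325 with 3 higher.

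Targets of ERK signalling stood lower in AG-haESC for 4 of 19 members, and 5 adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.565 with an estimated correlation, 0.0585 by fry). The immediate-early gene Egr1 was at 9.29 ± 0.64 against 12.25 ± 0.36, a difference of -2.96 ± 0.31 (adjusted p = 0.000144), and the cyclin Ccnd1 was lower by -1.90 ± 0.32 (0.00266). Of 16 primed epiblast genes 4 were lower, also adjusted over the list alone, among them the homeobox gene Otx2 by -1.35 ± 0.31 (0.0135) and Lef1 by -1.53 ± 0.29 (0.00484), and the list did not pass camera (adjusted p = 0.0645, and 0.0309 with no filter) but passed fry (0.0419). The DNA methyltransferase Dnmt3b was at 11.995 ± 0.39 against 12.56 ± 1.12 (adjusted p = 0.364). E14 replicate 3 stood apart in both lists, with an ERK value of 0.82 against -0.24 and -0.11 in the other E14 arrays and a primed value of 1.34 against 0.38 and 0.32. Without it 3 ERK targets were lower and 1 was higher, and the list's adjusted p was 0.297, and of the primed genes 3 were lower and 2 higher. The ERK call was also lost without AG-haESC replicate 4 (adjusted p = 0.0760), and 2 members were lower without AG-haESC replicate 1 or after quantile normalization. The primed list was called without AG-haESC replicate 3, E14 replicate 1 or E14 replicate 2 (adjusted p = 0.0461, 0.0170 and 0.0122). The growth protocol names the inhibitors CHIR99021 and PD0325901 for AG-haESC, and the medium of E14 is not given. An effect of the medium on both lists therefore cannot be told apart from a trait of the cells.

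Of 26 germline genes, 6 were higher and 2 lower in AG-haESC, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.511 with an estimated correlation, 0.0610 by fry). Of the 26, 4 are X-linked, so this list overlaps with the X-linked genes, and it was not tested without them. Besides Rhox6 and Rhox9, Sycp1, which builds the synaptonemal complex of meiosis, was at 10.81 ± 0.50 against 7.28 ± 0.58, a difference of 3.53 ± 0.32 (adjusted p = 5.28e-05). The lower members, chosen after their values were seen, were Sycp3 (-1.33 ± 0.24), also of the synaptonemal complex, and Dnd1 (-1.17 ± 0.30), and the Dnd1 call was lost without E14 replicate 1 or E14 replicate 2 (adjusted p = 0.0547 and 0.0631), which left 1 lower. E14 replicate 3 had a germline value of -0.43 against 1.02 and 1.09 in E14 replicates 1 and 2. With array weights 7 members were lower. Without E14 replicate 3, 5 were higher and 5 lower, and the list no longer passed (adjusted p = 0.0806).

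Fibroblast markers were higher in AG-haESC for 13 of 39 members and lower for 1, and for 15 and 1 adjusted over the list alone (camera adjusted p = 7.09e-08, adjusted p = 0.455 with an estimated correlation). Col1a1, a fibrillar collagen, was at least 3.89-fold higher, Postn, a matrix protein, at least 3.13-fold, and Ccn1, a secreted matrix regulator, was at 11.69 ± 0.40 against 8.98 ± 0.25, a difference of 2.71 ± 0.21 (adjusted p = 2.33e-05). Mmp2, chosen after its values were seen, was lower by -1.67 ± 0.28, and the fibroblast surface marker Thy1 differed by 0.42 ± 0.36 (adjusted p = 0.457). The list value was -0.73 ± 0.51 in AG-haESC, from -1.28 in AG-haESC replicate 1 to -0.013 in AG-haESC replicate 2, and -1.88 ± 0.72 in E14 (exact permutation p = 0.0714). In E14 replicate 3 it was -1.05, inside the range of AG-haESC, and without this array 24 members were higher and 2 lower, and with array weights 26 and 2.

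Of 26 Hox genes 7 were higher in AG-haESC, and 8 adjusted over the list alone (camera adjusted p = 0.00284, adjusted p = 0.165 with an estimated correlation). Hoxc4 was at least 2.35-fold higher, and 2 of the 7 lay below the array medians in both groups, so that no fold is given for them. The number higher was 4 without AG-haESC replicate 2, AG-haESC replicate 5 or E14 replicate 1 and with no trend, 2 with a pseudocount of 32 and 3 with a floor at the array median, where the camera call was lost (adjusted p = 0.152). Genes of the interferon response were higher for 5 of 24 members, also adjusted over the list alone (camera adjusted p = 0.000859, adjusted p = 0.511 with an estimated correlation). The interferon value was 0.49, 0.51 and 0.91 in AG-haESC replicates 1, 2 and 3 and -0.44 and -0.51 in AG-haESC replicates 4 and 5, against -0.92 to -0.57 in E14. The number higher was 1 without any 1 of AG-haESC replicates 1, 2 and 3 or of E14 replicates 1 and 2, and 8 without AG-haESC replicate 5. It was 3 with a floor, with no filter or in a 2-group fit, 1 with no trend and 12 with array weights, and fry did not call the list (adjusted p = 0.111). Of 17 glycolysis genes 2 were lower, also adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.717 with an estimated correlation, 0.254 by fry). Pdk1, a kinase that holds back pyruvate oxidation, was lower by -1.71 ± 0.33 on its brightest probe set, and another of its probe sets read 3.39 the other way (adjusted p = 0.0877). The glycolysis list was no longer called without E14 replicate 1 or E14 replicate 2 (adjusted p = 0.1001 and 0.0577), and both lower calls were lost with the mean of probe sets, where Pdk1 differed by -0.59 (adjusted p = 0.376). The number lower was 5 with array weights, 4 without E14 replicate 3 and 1 without any 1 of AG-haESC replicates 1, 2 and 3 or of E14 replicates 1 and 2.

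**Figure D4:**
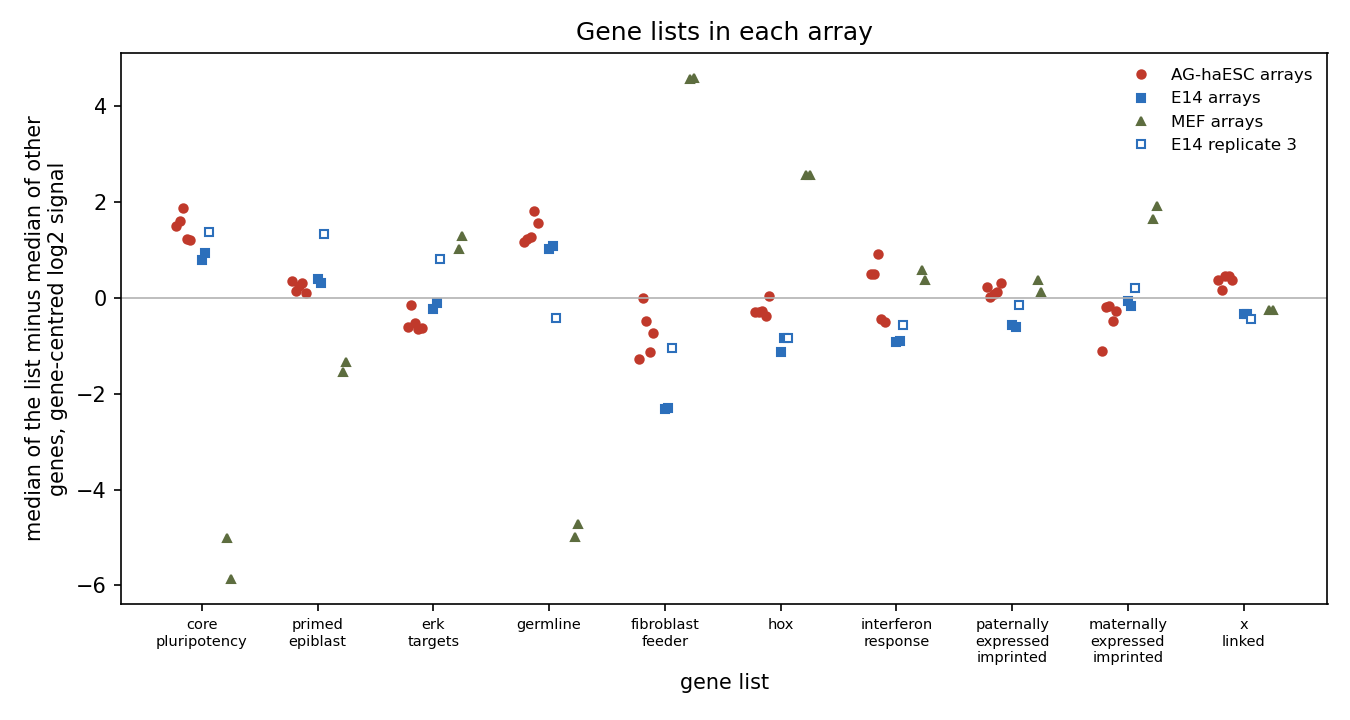
Value of 10 gene lists in each array, the median gene-centred log2 signal of the list minus that of the other genes (autosomal genes for the X), with 1 point per array and E14 replicate 3 open. In the germline list E14 replicate 3 lies at -0.43 and the other E14 arrays at 1.02 and 1.09, and in the fibroblast list the MEF arrays lie at 4.56 and 4.58.

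Camera called no other list for AG-haESC against E14, while fry called the epithelial junction list (adjusted p = 0.0465) and the WNT targets (0.0419) as lower in AG-haESC. Of 20 epithelial junction genes 3 were lower, and 4 adjusted over the list alone (camera adjusted p = 0.276), with Cldn6, a claudin, lower by -1.40 ± 0.27 and Cdh1, E-cadherin, at 12.92 ± 0.23 against 13.10 ± 0.23. Only 1 was lower without AG-haESC replicate 1, AG-haESC replicate 3 or E14 replicate 2, and 3 were higher without E14 replicate 3. Of 6 genes of the 2-cell stage 2 were higher and 1 was lower (camera adjusted p = 0.359), with Pramel7 at least 5.75-fold higher, and the 1 lower call was lost without any 1 array other than AG-haESC replicate 1 and E14 replicate 3. Of 21 lineage differentiation genes 2 were higher and 1 was lower (0.237), with Afp, alpha-fetoprotein, at least 2.28-fold higher and the laminin gene Lama1 at least 2.33-fold lower. Of 21 p53 targets 1 was higher, the apoptosis gene Pmaip1 by 2.22 ± 0.43, and 1 lower, Bbc3, by -1.14 ± 0.21 (0.735), and the cell cycle inhibitor Cdkn1a differed by 0.16 ± 0.49. Of 9 WNT targets 1 was higher, Apcdd1, by 1.67 ± 0.28, and 1 lower, Lef1 (0.545). Of 16 DNA methylation genes 1 was higher, Gadd45b, by 1.56 ± 0.36 (0.956), of 14 macrophage genes 1, Cd14, at least 1.73-fold (0.735), and of 16 muscle genes 1, Mylpf, by 1.15 ± 0.16 (0.545). Of 12 endothelial genes 1 was lower (0.545) and of 16 neural genes 1 (0.379). Adjusted over the list alone these counts were the same.

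In limma 0 of 24 G1/S genes, 0 of 27 G2/M genes and 0 of 43 oxidative phosphorylation genes changed (camera adjusted p = 0.323, 0.323 and 0.594). At an unadjusted p below 0.05, 3, 5 and 7 of them were higher and 6, 1 and 5 lower, and fry gave adjusted p = 0.307, 0.644 and 0.941. All groups were sorted on a peak of DNA content, so the cell cycle lists need not describe the unsorted cultures in any comparison. Without E14 replicate 3 there were 2 G2/M genes higher (camera adjusted p = 0.0236), 4 lineage genes and 3 DNA methylation genes higher. Without E14 replicate 1 there were 2 p53 targets higher and 2 WNT targets lower, and the neural call was lost, as it was without E14 replicate 2. Without AG-haESC replicate 4 there were 2 macrophage genes and 1 endothelial gene higher.

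Several of the largest changes outside the lists were autosomal. 2210409E12Rik was at 12.71 ± 0.33 against 6.39 ± 0.70, a difference of 6.32 ± 0.31 (adjusted p = 1.41e-06), and AA467197 was higher by 5.22 ± 0.49. Elobl, an elongin B-like gene, was at least 19.2-fold higher, the acyltransferase gene Gpat3 at least 16.9-fold and the transcription factor gene Gata3 at least 2.95-fold. Among the largest decreases Tmem87a was at 7.29 ± 0.28 against 10.89 ± 0.39, a difference of -3.60 ± 0.21, Kbtbd11 was lower by -4.10 ± 0.78 and Adam23 by -3.46 ± 0.61. Both lay below the array medians in most AG-haESC arrays, and with a floor at the array median the differences were -3.18 and -2.05. Without AG-haESC replicate 3 Kbtbd11 differed by -3.37, and without E14 replicate 3 AA467197 differed by 4.47. Nnt, the mitochondrial transhydrogenase gene, was at 9.48 ± 0.42 against 10.08 ± 0.10, a difference of -0.60 ± 0.21 that did not pass (adjusted p = 0.0828).

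The comparison of AG-haESC with MEF sets the haploid stem cells against cultured male embryonic fibroblasts. The MEF arrays also stood high in the macrophage list, with list values of 3.45 and 3.27, and in the muscle list, with 2.61 and 2.69. Whether other cell types were present in the MEF cultures was not tested. Of 31 pluripotency genes, 21 lay below the array medians in both MEF arrays. Pou5f1, a core pluripotency factor, was at 13.55 ± 0.12 against 2.64 ± 0.012 (mean log2 signal ± SD, n = 5 and n = 2) and thus at least 190-fold higher. Nanog was at least 281-fold higher, and Tdgf1, a co-receptor of Nodal signalling, at least 265-fold. Mgp, a matrix protein of mesenchymal cells, was at 3.53 ± 1.57 against 14.28 ± 0.15 and at least 320-fold lower. In all 5596 of 13251 genes changed, 2609 higher and 2987 lower in AG-haESC, and 7921 passed the adjusted p alone. After quantile normalization 2872 were higher and 2770 lower, so which direction holds more genes depends on the processing. Over all genes the arrays did not overlap for 9312, where chance gives 9.52%, and 1475 of the called differences are lower bounds.

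Of 31 pluripotency genes 29 were higher in AG-haESC and 1 was lower (camera adjusted p = 7.33e-17, adjusted p = 0.0573 with an estimated correlation). Sox2 was higher by 5.25 ± 0.19 (SE), Esrrb at least 43.4-fold and Zfp42 at least 47-fold, while Klf4, which fibroblasts also express, was at 12.996 ± 0.52 against 12.75 ± 0.0014 (adjusted p = 0.456). Of 26 germline genes 25 were higher (9.07e-12, adjusted p = 0.0762 with an estimated correlation), with Dazl, an RNA-binding gene of germ cells, at least 131-fold and Morc1 at least 56.9-fold. Trap1a, an X-linked gene, was at least 337-fold higher. Of 20 epithelial junction genes 15 were higher (2.55e-06, adjusted p = 0.0573 with an estimated correlation), Cdh1 at least 123-fold and Epcam at least 71.2-fold. Cell cycle genes were higher for 19 of 24 of G1/S (1.11e-12, adjusted p = 0.0762 with an estimated correlation) and 27 of 27 of G2/M (6.1e-14, also 0.0762), among them the replication genes Mcm5 by 2.73 ± 0.10 and Cdc6 by 3.22 ± 0.16 and the mitosis genes Cenpf by 3.38 ± 0.21 and Bub1 by 3.13 ± 0.21. These values are of cells sorted on a peak of DNA content and need not describe the unsorted cultures. Of 16 DNA methylation genes 9 were higher and 1 lower (0.0032, adjusted p = 0.0614 with an estimated correlation), with Dnmt3b higher by 4.87 ± 0.45 and Dnmt3l at least 63.9-fold. Of 16 primed genes 8 were higher and 3 lower (0.0247, adjusted p = 0.308 with an estimated correlation), with Otx2 at least 8.89-fold. Of 6 genes of the 2-cell stage 4 were higher (0.0289, adjusted p = 0.37 with an estimated correlation). The primed call was lost without MEF replicate 1 (0.0658) and that of the 2-cell stage without MEF replicate 2 (0.0758), with a floor (0.174) or with a stricter filter (0.0737).

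All 39 fibroblast genes were lower in AG-haESC (camera adjusted p = 1.18e-16, adjusted p = 0.0762 with an estimated correlation). Col1a1 was at 7.996 ± 0.95 against 13.62 ± 0.027, Postn was lower by -6.91 ± 0.67 and Thy1 by -5.57 ± 0.41, and the matrix gene Mfap4 was at least 68.3-fold lower. Of 26 Hox genes 21 were lower and 2 higher (1.62e-05, adjusted p = 0.0573 with an estimated correlation), with Hoxb6 at least 7.38-fold. Of 16 muscle genes 13 were lower and 1 higher (0.000764, adjusted p = 0.0812 with an estimated correlation), Myl1 at least 14.4-fold, and of 14 macrophage genes 10 were lower and 1 higher (0.00182, adjusted p = 0.0573 with an estimated correlation), the lysozyme gene Lyz2 at least 51.6-fold and outside the list its paralogue Lyz1 at least 102-fold. With MEF replicate 1 or MEF replicate 2 left out, genes seen in MEF alone fall under the filter, and the lower counts were 11 and 10 for Hox genes, 5 and 5 for muscle and 2 and 2 for macrophages, with camera adjusted p = 0.0658 and 0.0758 for muscle and 0.2004 and 0.244 for macrophages. ERK targets were lower for 11 of 19 and higher for 2 (0.0032, adjusted p = 0.327 with an estimated correlation), with Egr1 at 9.29 ± 0.64 against 14.17 ± 0.21, and 1 was higher without any 1 of AG-haESC replicates 1, 2 and 5 or of the MEF arrays.

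Of 26 maternally expressed imprinted genes 13 were lower in AG-haESC and 2 higher (camera adjusted p = 0.00302, adjusted p = 0.0718 with an estimated correlation), with Grb10, an adaptor that restrains growth, lower by -4.76 ± 0.22, Meg3 by -3.47 ± 0.34 and Igf2r by -2.96 ± 0.33. Of 22 paternally expressed genes 7 were lower and 3 higher (0.672, and 0.00181 by fry), with Igf2 at 8.80 ± 0.66 against 14.55 ± 0.065 and Peg3 lower by -1.18 ± 0.21, and Snrpn was at 5.78 ± 1.19 against 4.36 ± 1.21 (adjusted p = 0.132; 0.0128 without AG-haESC replicate 5). X-linked genes were higher for 170 of 465 and lower for 73 (0.000788, adjusted p = 0.396 with an estimated correlation), and the X value was 0.36 ± 0.12 against -0.26 ± 0.0072, a difference of 0.62 (exact permutation p = 0.0476, the smallest it can give). Xist was at least 6.53-fold higher in AG-haESC. Of 4 Y-linked genes 3 were lower (0.0259, adjusted p = 0.173 with an estimated correlation), Eif2s3y at least 37.8-fold, Uty at least 9.33-fold and Kdm5d at least 12.7-fold.

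Glycolysis genes were higher in AG-haESC for 5 of 17 and lower for 1 (camera adjusted p = 0.0259, adjusted p = 0.705 with an estimated correlation), with the glucose transporter gene Slc2a3 higher by 3.92 ± 0.19, and the call was lost without MEF replicate 1 (0.0522) or MEF replicate 2 (0.0743) and after quantile normalization (0.0501). Oxidative phosphorylation genes were higher for 3 of 43 (2.58e-05, adjusted p = 0.469 with an estimated correlation), with Cox7c higher by 2.20 ± 0.21. Camera did not call the remaining lists, while fry called the lineage list as higher in AG-haESC (adjusted p = 0.0352). Of 21 lineage genes 7 were higher and 6 lower (0.8), with Col4a1 lower by -4.08 ± 0.36, of 9 WNT targets 3 and 2 (0.793), with Lgr5 at least 8.81-fold lower, of 24 interferon genes 2 and 4 (0.601), with Oas2 at least 3.05-fold higher and Ifit2 at least 9.7-fold lower, and of 12 endothelial genes 4 and 4 (0.798), with Pecam1 at least 7-fold higher. Of 16 neural genes 3 were higher and 5 lower (0.672), with Fabp7 at least 39.8-fold lower, and of 21 p53 targets 3 and 4 (0.828), with Fas at least 5.46-fold lower. Cdkn1a was lower by -1.47 ± 0.56 (adjusted p = 0.0382), a call lost without AG-haESC replicate 3 or either MEF array (0.0696, 0.0861 and 0.218), and Nnt was at 9.48 ± 0.42 against 11.41 ± 0.13 (adjusted p = 4.14e-05). Left-out arrays moved some of these counts by over 1.5 times. Without AG-haESC replicate 3 there were 7 interferon genes lower and without AG-haESC replicate 4 there was 1 WNT target lower. Without MEF replicate 1 and MEF replicate 2 the p53 targets numbered 1 and 1 higher and 2 and 1 lower, 1 Hox gene was higher, the endothelial genes were 1 and 1 lower, both lower calls of the WNT targets were lost, and the neural genes were 1 and 3 higher and 3 and 3 lower, with fewer genes tested. Adjusted over the list alone the counts were 9 and 3 for primed genes, 16 higher for epithelial junctions, 2 and 22 for Hox genes, 2 and 3 for p53 targets, 20 higher for G1/S and 171 and 74 for X-linked genes, and as above for the other lists.

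The comparison of E14 with MEF gives the same contrast for diploid stem cells, in male cells on both sides. Here too 21 of 31 pluripotency genes lay below the array medians in both MEF arrays. Pou5f1 was at 13.52 ± 0.27 against 2.64 ± 0.012 (mean log2 signal ± SD, n = 3 and n = 2) and at least 186-fold higher in E14, Nanog at least 154-fold and Tdgf1 at least 292-fold. Postn was at least 377-fold lower in E14 and Col1a1 at least 191-fold. In all 5581 genes changed, 2764 higher and 2817 lower in E14, and 7595 passed the adjusted p alone. The balance turned after quantile normalization, with 2951 higher and 2645 lower. Over all genes the arrays did not overlap for 9797, where chance gives 20%, and 1535 of the called differences are lower bounds.

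Of 31 pluripotency genes 29 were higher in E14 and 1 was lower (camera adjusted p = 2.55e-16, and 0.0347 with an estimated correlation). Sox2 was higher by 5.29 ± 0.20 (SE), Zfp42 at least 139-fold and Esrrb at least 40.5-fold, and Klf4 differed by -0.050 ± 0.30 (adjusted p = 0.898). Of 26 germline genes 25 were higher (4.35e-10, adjusted p = 0.089 with an estimated correlation), Dazl at least 34.8-fold (21.9, 20.7 and 93.1 without E14 replicates 1, 2 and 3) and Morc1 at least 53.1-fold, and Trap1a was at least 187-fold higher. Of 20 epithelial junction genes 16 were higher (7.22e-07, adjusted p = 0.0519 with an estimated correlation), Cdh1 at least 138-fold and Epcam at least 98.2-fold. Cell cycle genes were higher for 22 of 24 of G1/S (1.04e-12) and 27 of 27 of G2/M (5.15e-13, adjusted p = 0.0853 with an estimated correlation for both), with Mcm5 higher by 3.01 ± 0.11, Cdc6 by 2.97 ± 0.17, Ttk by 3.66 ± 0.19 and Bub1 by 3.27 ± 0.22. These values too are of cells sorted on a peak of DNA content. Of 16 DNA methylation genes 9 were higher and 1 lower (0.00637, adjusted p = 0.0778 with an estimated correlation), Dnmt3b by 5.44 ± 0.49 and Dnmt3l at least 37.9-fold. Of 16 primed genes 11 were higher and 2 lower (0.0102, adjusted p = 0.222 with an estimated correlation), Otx2 at least 22.6-fold. Glycolysis genes were higher for 9 of 17 (0.00183, adjusted p = 0.534 with an estimated correlation), Slc2a3 by 3.93 ± 0.20 and Slc2a1 by 2.71 ± 0.29. Oxidative phosphorylation genes were higher for 2 of 43 (8.81e-05, adjusted p = 0.534 with an estimated correlation), Cox7c by 1.68 ± 0.23.

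All 39 fibroblast genes were lower in E14 (camera adjusted p = 2.04e-20, adjusted p = 0.0802 with an estimated correlation), Thy1 by -5.999 ± 0.45 and Mfap4 at least 64.6-fold. Tgfb3, a growth factor of the TGF-beta family, was at least 74.8-fold lower and Lyz1 at least 96.4-fold. Of 26 Hox genes 23 were lower (1.88e-07, and 0.0347 with an estimated correlation), Hoxb5 at least 3.02-fold, of 16 muscle genes 13 were lower and 1 higher (0.00043, adjusted p = 0.0853 with an estimated correlation), Myl1 at least 13.6-fold, and of 14 macrophage genes 9 were lower (0.00156, adjusted p = 0.0519 with an estimated correlation), Lyz2 at least 48.8-fold. Left-out MEF arrays reduced these counts, with fewer genes tested, to 14 and 13 for Hox genes, 4 and 4 for muscle (camera adjusted p = 0.0546 and 0.0626) and 2 and 2 for macrophages (0.115 and 0.148), and without E14 replicate 3 there were 2 Hox genes higher. ERK targets were lower for 8 of 19 and higher for 1 (0.045, adjusted p = 0.534 with an estimated correlation), Phlda1 by -3.27 ± 0.38, and lower for 4 and 3 without MEF replicate 1 and MEF replicate 2, and 2 were higher without E14 replicate 1. The ERK call was lost without E14 replicate 1 or E14 replicate 2 (0.103 and 0.109), with a pseudocount (0.0534), with a floor (0.0588) and with a stricter filter (0.0790). Interferon genes were lower for 9 of 24 and higher for 2 (0.0332, adjusted p = 0.534 with an estimated correlation), Ifit3 at least 4.4-fold, and Oas2 was at least 1.6-fold higher. Their number higher was 1 without E14 replicate 2 or either MEF array, and the call was lost without E14 replicate 1 (0.0624) or with a stricter filter (0.0507).

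Of 26 maternally expressed imprinted genes 14 were lower in E14 and 4 higher (camera adjusted p = 0.0133, adjusted p = 0.0875 with an estimated correlation), with Phlda2 higher by 5.40 ± 0.33, Meg3 lower by -1.97 ± 0.37 and Igf2r by -2.75 ± 0.36. The counts were 9 lower without either MEF array, and 2 were higher without E14 replicate 2 or MEF replicate 2. Of 22 paternally expressed genes 10 were lower and 3 higher (0.0865, 4.0e-06 by fry, 0.0409 without E14 replicate 3, 0.0422 with no filter and 0.0421 with the mean of probe sets), with Igf2 lower by -6.45 ± 0.57, Plagl1 by -3.42 ± 0.23 and Peg3 by -2.92 ± 0.23, and Snrpn at 6.21 ± 0.59 against 4.36 ± 1.21 (adjusted p = 0.0783). X-linked genes went both ways, with 110 of 465 higher and 122 lower (0.718), and the X value differed by -0.11 (exact permutation p = 0.1, the smallest it can give). Xist was at least 3.39-fold higher in E14. Of 4 Y-linked genes 1 was higher and 1 lower (0.827), both calls were lost without either MEF array, and the 1 higher was lost without E14 replicate 1 or E14 replicate 2. Eif2s3y differed by 0.61 ± 1.08 and Uty by -0.91 ± 0.70 (adjusted p = 0.651 and 0.287), and Kdm5d was lower by -3.33 ± 0.99 (adjusted p = 0.0133), lost without MEF replicate 1 or MEF replicate 2 (0.0748 and 0.0701). It read 3.62 in E14 replicate 3 against 7.61 and 7.65 in E14 replicates 1 and 2, and without E14 replicate 3 the difference was -1.99.

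Camera did not call the remaining lists for E14 against MEF, while fry called the WNT targets (adjusted p = 0.00452), the genes of the 2-cell stage (0.00737), and the endothelial and neural lists (0.0288 for both), all as higher in E14. For the neural list the median difference was -0.35, and the direction given by camera was lower in E14. Of 21 lineage genes 8 were higher and 6 lower (camera adjusted p = 0.948), with Col4a1 lower by -4.77 ± 0.40, of 9 WNT targets 4 and 3 (0.823), with Lgr5 at least 8.33-fold lower, of 12 endothelial genes 5 and 2 (0.639), with Pecam1 at least 6.64-fold higher, of 16 neural genes 6 and 6 (0.851), with Fabp7 at least 37.7-fold lower, and of 21 p53 targets 2 and 4 (0.823), with Fas at least 5.17-fold lower. Of 6 genes of the 2-cell stage 3 were higher (0.153). Cdkn1a was lower by -1.63 ± 0.61 (adjusted p = 0.0374), a call lost without E14 replicate 3 or either MEF array (between 0.0786 and 0.190), and Nnt was lower by -1.33 ± 0.27 (adjusted p = 0.00131). Without MEF replicate 1 there were 4 lineage, 3 endothelial and 2 neural genes higher and 1 WNT target, 1 endothelial gene and 1 p53 target lower, and both higher p53 calls were lost. Without MEF replicate 2 there were 5 lineage and 2 endothelial genes higher, 2 neural genes, 1 endothelial gene and 1 p53 target lower, and the 3 lower WNT calls were lost. There were 5 lineage genes higher without E14 replicate 1 or E14 replicate 2. Without E14 replicate 3 there were 1 WNT target, 2 p53 targets and 2 DNA methylation genes lower and 4 p53 targets higher. Adjusted over the list alone the counts were 2 and 2 for p53 targets, 10 and 1 for glycolysis and 10 lower for macrophages, and as above for the other lists.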

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

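The test of the X-linked genes over the genes above the median in all arrays and the MEF shares needed by fibroblast and other abundant MEF genes were chosen only after the result was seen, while quantile normalization was chosen before and only its bound for the X-linked genes was set after.

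The first pattern is the higher signal of X-linked genes in AG-haESC. A haploid cell with an X chromosome holds 1 X per set of autosomes, where a male diploid cell holds 1 X per 2 sets, which predicted a difference of 0.3 log2 units or more with no overlap, and the measured difference was 0.737. Unequal distributions of signal between arrays are argued against, since the difference was 0.711 after quantile normalization. A few strongly changed gene families are argued against by the breadth of the shift, with a positive difference in 83.9% of X-linked and 41.1% of autosomal genes. Over 304 X-linked and 8642 autosomal genes above the array median in all 10 arrays the X difference was 0.706. There the lowest AG-haESC array was at 0.095 and the highest E14 array at -0.36. A median moves little with a few families, so this last check could hardly have come out otherwise. A candidate explanation is therefore the dose of the X relative to the autosomes, as a hypothesis. Strain, parental origin, ploidy and passage differ together, and the culture of E14 is not known. The difference of AG-haESC from MEF, 0.62, shares the same AG-haESC arrays.

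The second pattern is the fibroblast list, whose members stood higher in AG-haESC by a median of 1.07. RNA of feeder cells in the sorted AG-haESC predicted a shift that rises with each member's excess in MEF over stem cells, with a correlation above 0.5, and the Spearman correlation over the 39 members was 0.0549 (95% bootstrap interval -0.278 to 0.376, permutation p = 0.739). The correlation fell short of that prediction and lay below the bound of 0.2 set for absence, but the interval reached above that bound. The stem cell level in the excess includes the AG-haESC arrays. A member raised in them thus has a lower excess, which works against a positive correlation. The interval and the p are over genes and do not carry the spread between arrays. With the MEF arrays as a stand-in for feeder cells, the 13 higher members would need a MEF share of 2.52% in the median, from 0.728% to 31.1%. The other 26 members would need 0.745%, from -4.996% to 4.67%, with 7 of them at 0 or less, among them Mgp at -0.0850%. All 39 members gave a median of 0.979%, and 57 other genes abundant in MEF would need 0.551%. Of the 57, 33 lay at least 1 log2 unit below the level that a share of 2.52% would give. The 13 members were picked for being higher in these data, which raises their share, so this shortfall is no evidence against feeder RNA. Of the 39 members 21 lay above the array median in all E14 arrays, whose source could be either, and the sort for the 1n peak would remove diploid feeder cells. Feeder RNA and expression by the stem cells themselves cannot be told apart, because the profile of the feeder cells and the culture of E14 are not known here.

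The third pattern is the number of genes changed between AG-haESC and E14. Of the 56 splits of the 8 arrays into 5 and 3, only the real 1 gave as many as 1102 genes, and the highest of the others gave 38. That share of the splits, 0.0179, is the smallest that 56 splits can give. A chance division of the arrays is therefore argued against but not excluded. Every other split mixes the groups, which adds their difference to the spread and lowers the count.

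Single AG-haESC lines stood away from the other 4 in 14 of 127 values tested (per-array list values, named genes and quality measures), by a gap of more than 0.71 of the range of the 5 lines. Chance alone picks about 1 in 20 groups. Among lists, the ERK targets of AG-haESC replicate 2 stood at -0.16 against -0.65 to -0.52 in the other lines (0.729 of the range), the Hox genes of AG-haESC replicate 5 at 0.046 against -0.38 to -0.28 (0.777) and its G1/S genes at 0.13 against 0.42 to 0.52 (0.729). In AG-haESC replicate 4, Cdkn1c stood at 7.67 against 5.74 to 6.20 (0.761), Nnt at 8.75 against 9.57 to 9.74 (0.827), Prdm14 at 10.37 against 11.10 to 11.40 (0.712) and Hoxb5, below the array medians in all lines, at 4.53 against 1.85 to 2.52 (0.749). In AG-haESC replicate 3, Lef1 stood at 7.09 against 8.20 to 8.48 (0.802) and Kbtbd11, below the array median in this line, at 2.16 against 5.40 to 6.32 (0.779). In AG-haESC replicate 1, Phlda2 stood at 8.24 against 9.06 to 9.35 (0.741), Dnmt3l at 11.48 against 12.01 to 12.18 (0.759), and the ratio of the 3' to the 5' probe set of the dap spike-in control at 5.81 against 1.99 to 2.45 (0.879). In AG-haESC replicate 5, Pou5f1 stood at 13.35 against 13.56 to 13.63 (0.732) and Snrpn, below the array median in this line, at 3.76 against 5.90 to 6.76 (0.712).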

How the results depend on the processing

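All alternatives were planned before the data were examined, except the counts of list members under each setting, the array similarity under each setting and the fit of the same 4 arrays with no block, which were chosen after seeing the data. The number of genes changed for AG-haESC against E14 stayed within 1.5 times 1102 under quantile normalization (1102), a pseudocount (929), a floor (951), no filter (1018), a stricter filter (953), the mean of probe sets (1106), a 2-group fit (1024) and no trend (1022), and 1055 of the genes were called the same way after quantile normalization. It was 1997 over all probe sets, 2101 with no minimum fold and 613 at an adjusted p under 0.01, since those settings test more features or move the threshold, and 1707 with array weights, where the cause was not tested. Over all probe sets the counts were 10769 for AG-haESC against MEF and 10688 for E14 against MEF. Leaving out 1 array gave from 844 (without E14 replicate 1) to 1341 (without E14 replicate 3) for AG-haESC against E14, from 4510 to 5604 for AG-haESC against MEF and from 4453 to 5536 for E14 against MEF, where a lone MEF array was assumed to vary like the other groups. With the replicate block over the 4 arrays of E14 and MEF that share a number, 5615 genes changed, and 5696 for the same arrays with no block, but the numbers did not pair the arrays (r = -0.026 across genes between their deviations). The X difference ranged from 0.62 to 0.77 over settings and from 0.70 to 0.79 over left-out arrays, that of paternally expressed genes from 0.39 to 0.74 and from 0.48 to 0.68, both with exact p below 0.05 throughout, and that of maternally expressed genes from -0.43 to -0.27 and from -0.57 to -0.24, never past 0.05. With an estimated correlation 0 lists passed camera for AG-haESC against E14 in place of 10 (5 at an unadjusted p under 0.05, 9 by fry), 0 in place of 18 for AG-haESC against MEF (11 unadjusted, 20 by fry) and 2 in place of 16 for E14 against MEF (11 unadjusted, 21 by fry). The similarity of AG-haESC and E14 was 0.940 with a pseudocount, 0.944 with a floor and 0.899 with the mean of probe sets, against 0.914. Among the called genes named in the text, Pdk1 was the 1 whose direction reversed, at 3.39 in AG-haESC minus E14 on another probe set, and the cause was not tested. Of 168 gene values named in the text, 136 kept their call in every setting other than the changed thresholds, and 32 lost or gained it in some. The settings with no minimum fold and with an adjusted p under 0.01 were left out of these counts. Signals below the array medians limit sizes to lower bounds, for 210 of the 1102 genes.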

Other observations

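The test of Nnt was planned before the data were examined, and the values of single lines below were chosen for description only after they were seen.

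Gene groups also differed between arrays within a group. The macrophage list, of which 10 of 14 members were lower in AG-haESC than in MEF, reached 0.11 in AG-haESC replicate 2 against -1.04 to -0.45 in the other lines. The list of p53 targets was at -0.94 in AG-haESC replicate 4 and between 0.011 and 0.55 in the other lines, and Cdkn1a, a p53 target that halts the cell cycle, had an SD of 0.96 log2 units over the 5 lines. Genes of the 2-cell stage ranged from 0.13 in AG-haESC replicate 4 to 1.47 in AG-haESC replicate 2. The neural list stood at 0.86 in E14 replicate 3 against -0.31 and -0.29 in E14 replicates 1 and 2, and the DNA methylation list at 0.60 against 0.26 and 0.20. Dazl, an RNA-binding gene of germ cells, had an SD of 2.46 over the E14 arrays and 0.26 over the AG-haESC lines.

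C57BL/6J mice carry a deletion in Nnt, so a hypothesis was that Nnt is lower in every AG-haESC array than in every E14 array, with an adjusted p under 0.05, while a difference under 1 log2 unit or an overlap of the arrays was to count against it. The difference was -0.597 ± 0.214 (SE), with no overlap between the arrays, and did not pass (adjusted p = 0.0828). So the predicted significance was not reached, and the size met the bound of 1 set for absence, though by less than 2 SE. That bound also took the probe set to lie in the deleted part, and its place relative to the deletion is not given in the sources used here. An effect of the strain may therefore be present or absent at this probe set.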
